A study of Mus musculus with 3 samples.

How the data were processed

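CD45+ cells were sorted by flow cytometry from the colon of C57BL/6 mice and made into 10x Genomics 3′ libraries with molecular identifiers, per the labels' protocols. The labels call the mice male, which the Xist and Y-linked transcripts given at the end go against. The labels give 1 library from healthy colon (C), 1 from colon with low-grade (T1) and 1 from colon with high-grade (T3) intraepithelial neoplasia after AOM and DSS, and these were the groups compared. The authors deposited whole-number UMI counts per gene and barcode, without normalization. The submitters' processing notes name CASAVA 1.8, Cell Ranger 3.1.0, Seurat 3.1.4 and the build GRCm38 without giving their roles, and the version 3.1.0 also stands in the matrices, per the file headers. The aligner settings and the gene annotation are not given in the sources used here. Every deposited barcode held at least 500 UMIs, so a filter on barcodes had been applied before deposit, and the level of RNA in empty droplets was not analysed here. Whether reads within introns were counted is not stated, and overlapping genes and near-identical copies are therefore uncertain.

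All values were computed from the deposited counts. Barcodes with fewer than 200 detected genes (164, 292 and 173 in C, T1 and T3) or more than 20% mitochondrial counts (1896, 2396 and 1142) were left out. Scrublet, run per library in scanpy 1.11.5, called 92, 3 and 1 doublets, which were removed. A call of 0.0488% in T1 and 0.0220% in T3 is too low for libraries of this size, so the caller did not work there and doublets remain in the data. This left 16594 cells and 14447 genes found in at least 10 cells, of 30905 in the files. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken. Variable, diversity and joining segments of immunoglobulins and T-cell receptors, mitochondrial genes and ribosomal protein genes were left out. Lars2, the rRNA-overlapping transcripts and the regulatory B-cell list were left out too, whereas constant genes and other studied genes could be used. Clusters came from 30 principal components, 15 exact nearest neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, seed 0), without integration of the libraries. They numbered 27.

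Clusters were named from marker genes fixed before the data were examined, and are called X-like for that reason. A cluster took the class with the highest mean marker score if the score was at least 0.8 and led the next class by 0.4, if 3 markers were found in at least 5% of its cells, and if fewer than 3 of its 10 leading genes over the other lineages were markers of another class. T-like and innate lymphoid clusters were parted by whether more than 50% of cells had a CD3 chain UMI. A cluster whose median UMI count lay under 1/3 of its library's median stayed unnamed. These thresholds were set after the clusters had been seen and were revised several times. The authors' own cell annotation was not used here.

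For each class and library, UMIs were summed and given as CPM, each gene's part of the summed UMIs. The fold between libraries has an exact conditional interval at 95%, and shares have exact Clopper-Pearson intervals. The interval of a log2 ratio of shares is a normal approximation from the binomial counts. With 1 library per group these intervals cover counting error only, and no p-value was computed. A gene was taken as higher or lower when its CPM was at least 2-fold apart, it had at least 100 UMIs over the 2 libraries and its interval excluded no difference. Genes were named by a rule fixed before the data were examined, which took in each class up to 10 genes higher and 10 lower in both T1 and T3 and up to 5 higher and 5 lower in T3 than in T1. They had to be found in at least 5% of the cells of the class in 1 library. Mitochondrial, ribosomal protein, receptor variable and predicted genes were left out, as were genes under 20% of their CPM in another class of that library. The order was by the smaller of the 2 absolute log2 ratios, or by the ratio of T3 to T1. Lars2 and members of 25 gene lists, also fixed before the data were examined, could be named as well. Some genes that the rule picked are not reported here. Genes were matched by the deposited symbols, under which Areg, Bcl11b and Siglecf have other names and Aldoa and Nnt share theirs with a second gene ID, so these were not matched as markers or list members. A list's median over members with at least 20 UMIs was set against 10000 random lists matched on expression, as a description of these libraries. Counts of members past the rule are of those with at least 100 UMIs. A share with 0 cells was given the upper limit of its exact interval. Shares of cells with a UMI were computed after drawing each cell down to 1000 UMIs.

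Overlaps of the comparisons with C were set against independent lists and against 20 draws of unchanged libraries. These draws held counting noise only, without differences between mice or libraries. Coordinates and the search for shared sequence used the GENCODE vM21 annotation of GRCm38, the build named in the notes, with blastn 2.17.0. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

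The gene rule was tested on simulated data with 200 changed genes. In B-like cells, T1 against C, it found 2.94% of genes changed 1.5-fold, 92.4% of those changed 3-fold and 92.4% of those changed 4-fold among 9069 genes, and 0 of 8880 unchanged ones. In B-like cells, T3 against C, the values were 2.94%, 97.0% and 100% of 8120 genes, with 12 of 7921 unchanged genes found. In T-like cells they were 2.94%, 100% and 92.4% of 9144 genes for T1 (0 of 8950) and 2.94%, 93.9% and 92.4% of 8774 genes for T3 (2 of 8583). Changes below 2-fold are therefore mostly outside what the rule reports. The simulated counts held counting noise only, so they do not measure false calls that come from differences between libraries. A simulated list of 20 doubled genes lay at percentile 100 in all 4 comparisons, and an unchanged list at 19.6 and 25.2 in B-like cells of T1 and T3 and at 12.25 and 96.85 in T-like cells, so a percentile near 97 can occur without a change. In a simulation of thinning with 2000 deep and 2000 shallow cells, shares of 91.75% and 62.5% became 38.8% and 40.25%.

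Alternatives chosen before the data were examined were a mitochondrial limit of 10%, minimums of 500 genes and maximums of 5000 genes per cell, doublets kept, resolutions of 0.5 and 2, all variable genes, principal components centred per library, TMM factors, a total without immunoglobulin, mitochondrial and rRNA-overlapping genes, a mean over cells, other thinning depths, UMI minimums of 50 and 300 and a fold of 1.5. Alternatives added afterwards were the removal of the cells with the highest doublet scores (0.8% per 1000 cells), stricter naming, shares of named cells, the low-UMI cluster kept in the B-like cells and cells of at least 2000 UMIs.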

Results

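CD45+ leukocytes sorted from mouse colon were profiled by droplet single-cell RNA sequencing of transcript 3′ ends in 3 libraries. The healthy library (C) came from normal colon. The other libraries came from the azoxymethane and dextran sulfate sodium (AOM/DSS) model, in which a carcinogen given at 12 mg/kg is followed by 3 cycles of 2.5% DSS, an irritant of the colon lining. Library T1 held cells from colon with low-grade intraepithelial neoplasia and T3 cells from colon with high-grade intraepithelial neoplasia. The labels give T1 and T3 the same AOM and DSS course and give none for C. Neoplasia and the treatment with AOM and DSS therefore cannot be told apart in any comparison with C. The labels give 1 library per group and do not say how many mice each library holds. There are no replicates, so no difference below has a replicate check and no test between conditions was made. The 95% intervals cover counting error only; those of log2 ratios of cell shares use a normal approximation and the others are exact. The deposited counts held 7903 barcodes and 35489195 unique molecular identifiers (UMIs) in C, 8566 barcodes and 37208603 UMIs in T1, and 5779 barcodes and 15898397 UMIs in T3. After filtering, 5912, 6140 and 4542 cells remained in C, T1 and T3, with a median of 4913, 5272 and 1801 UMIs per cell, so T3 was the shallowest library.

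The comparison of cell classes asked which leukocytes of the CD45+ gate differed in share between healthy colon and the neoplastic stages. B-like cells, named from Cd79a, Ms4a1, Pax5 and related markers, were 49.5% of the cells of C (95% interval 48.2 to 50.8), 50.3% of T1 (49.0 to 51.6) and 19.7% of T3 (18.6 to 20.9), a 2.51-fold lower share in T3 than in C. T-like cells were 35.9%, 36.5% and 42.9%. Neutrophil-like cells, the short-lived phagocytes of acute inflammation, were 6 cells (0.101%) in C, 6 cells (0.0977%) in T1 and 55 cells (1.21%) in T3, and the log2 ratio of T3 to C was 3.58 [2.36, 4.79]. Plasma-cell-like cells, the antibody secretors of the gut wall, were 91 cells (1.54%) in C, 79 cells (1.29%) in T1 and 5 cells (0.110%) in T3, with a log2 ratio to C of −3.81 [−5.10, −2.51]. ILC2-like cells, innate lymphoid cells of type 2 immunity, were 146, 80 and 7 cells, or 2.47%, 1.30% and 0.154%, with log2 ratios to C of −0.92 [−1.31, −0.53] in T1 and −4.00 [−5.09, −2.91] in T3.

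NK/ILC1-like cells were also less frequent, at 1.57% of C, 0.733% of T1 and 0.264% of T3, with log2 ratios to C of −1.10 [−1.61, −0.59] and −2.57 [−3.44, −1.71]. Mononuclear-phagocyte-like cells numbered 46, 43 and 16, or 0.778%, 0.70% and 0.352% of cells. Mast-cell-like cells numbered 16 in C and 8 in T1, and 0 of 4542 cells in T3, where the exact interval reached up to 0.0812%. Erythroid-like cells, which a CD45+ gate would largely exclude, numbered 0 in C and T1 and 13 (0.286%) in T3. Cells without a class made up 7.93% of C, 8.93% of T1 and 35.0% of T3, and they lower every share in T3. They included cluster 2 (1, 0 and 1180 cells), in which haemoglobin transcripts stood beside T-cell transcripts and which held 26.0% of T3. The neutrophil markers S100a8, S100a9 and G0s2 and the cytokine gene Il1b were also among its leading genes. Neutrophil transcripts in T3 were therefore not confined to the neutrophil-like class. Naming thresholds set after the clusters were seen kept 4 clusters out of the classes. Besides cluster 2 (0.0169% of C and 0% of T1), these were low-UMI B-like cluster 5, with 3.50%, 5.59% and 8.12% of C, T1 and T3, the low-UMI cluster 11 led by Krt8, Lgals4 and Krt19, with 4.41%, 2.57% and 0.374%, and the mixed B-T cluster 22, with 0%, 0.765% and 0.484%. Cluster 22 had a CD3 UMI in 94.2% of its cells, and its leading genes over other lineages included Ebf1 and Cd79a. Doublets were called and removed in 92 cells of C, 3 of T1 and 1 of T3, so more may remain in T1 and T3. Whether cluster 22 holds doublets was not tested. Among named cells alone the log2 ratio of T3 to C was −0.83 for the B-like and 0.76 for the T-like share, against −1.33 [−1.42, −1.23] and 0.26 [0.19, 0.33] among all cells. Stricter naming set aside any cluster whose 10 leading genes over all other cells held more markers of another class than of its own. The B-like log2 ratio was then −0.98 in T1, against 0.02 [−0.03, 0.08], and −2.06 in T3. This set aside the large B-like cluster 1, which had 0 B-cell markers among those genes. Over the other lineages alone, its leading genes included Cd79a, Ms4a1, Fcmr and Bank1.

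**Figure D1:**
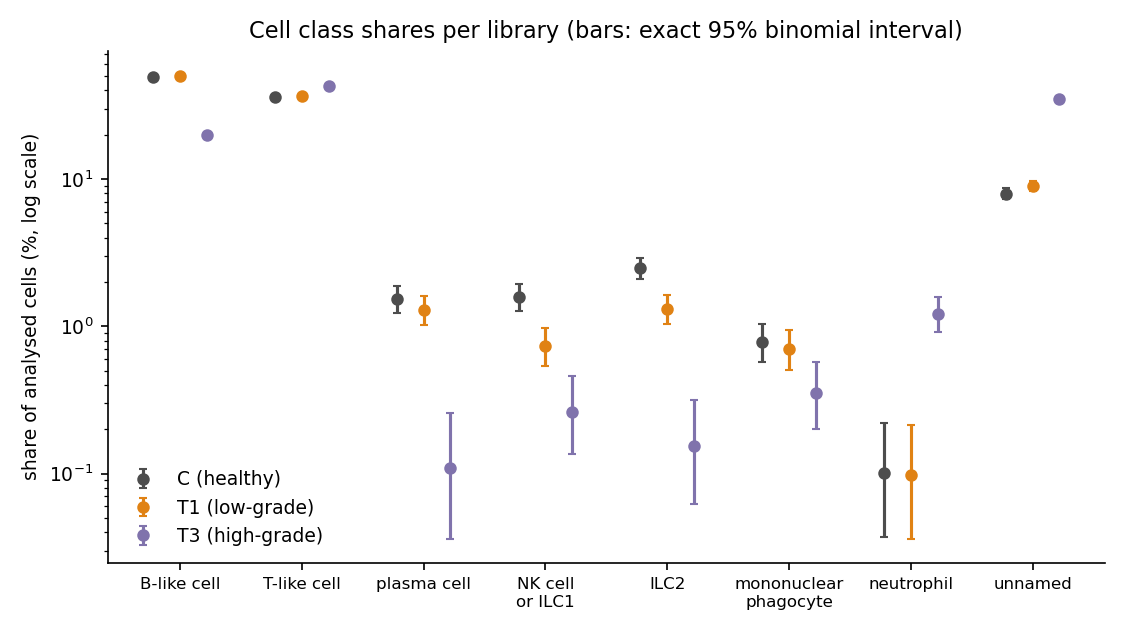
Share of each cell class among all analysed cells of C, T1 and T3, in percent on a log axis; points are shares and bars are exact Clopper-Pearson 95% intervals for counting error. The neutrophil-like share was highest in T3 (1.21%), and the plasma-cell-like, ILC2-like and NK/ILC1-like shares were lowest there.

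The comparison of T-like cells of T1 with those of C asked which T-cell programmes differed in the low-grade library. T-like cells of T1 carried more regulatory and type 17 transcripts and fewer transcripts of CD8 and gamma-delta cytotoxic cells. Foxp3, the transcription factor of regulatory T cells, was higher by a log2 ratio of 2.31 [2.05, 2.57] in CPM, the summed UMIs of a class scaled to a common total, Ctla4, an inhibitory receptor, by 1.97 [1.90, 2.04], and Il10, an anti-inflammatory cytokine, by 2.23 [2.07, 2.39]. Among type 17 cytokines the log2 ratio was 2.87 [2.68, 3.06] for Il17a and 4.23 [3.75, 4.77] for Il22. Foxp3 lies on chromosome X from 7573644 to 7595245 and Il10 on chromosome 1 from 131019845 to 131024974 (GRCm38). In contrast, Cd8a fell by 1.26 on the log2 scale, Trdc, a gamma-delta T-cell receptor constant gene, fell by 1.58 and Ifng fell by 1.21. In the regulatory T-cell list, 11 of 14 measured members rose and 0 fell, with a median log2 ratio of 1.77 that lay at the 100th percentile of 10000 expression-matched random lists. Tnfrsf4 (2.19), Icos (1.95) and Il2ra (1.86) were among them, whereas Ikzf2 had a log2 ratio of −0.73. In the type 17 list 8 of 10 members rose and 1 fell, the median was 2.04 and the percentile 100. The member that fell was Csf2, a granulocyte-macrophage growth factor, at −2.43 [−2.89, −2.00].

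In the cytotoxic effector list 7 of 13 members fell in T1 and 0 rose, with a median of −0.71 at percentile 0; Klrd1 fell by 1.87 and Ccl5 by 1.51 on the log2 scale, whereas Gzmb had a log2 ratio of 0.41. Of the inhibitory receptors, 4 of 12 rose and 3 fell (median 0.73, percentile 100); Havcr2 rose by 2.97 and Cd160 fell by 1.95. Hypoxia and glycolysis genes had a median of 0.39 (percentile 99.99), with 5 of 15 higher and 0 lower, including Ndrg1 (2.31), Hilpda (1.27) and Slc2a1 (1.20). Immediate early genes, which also respond to tissue dissociation, had a median of −0.67 at percentile 0, with 7 of 17 lower. The antigen presentation genes of MHC class II had a median of 1.09 (percentile 100) and 7 of 11 were higher, among them Cd74 (1.35), a transcript that B cells also carry in abundance. Immunoglobulin constant genes had a median of 0.31 (percentile 99.86, 1 of 9 higher and 0 lower) and naive B-cell genes of 0.30 (percentile 99.91, 1 of 10 higher and 1 lower), and B-cell RNA in T-like barcodes was not separated from expression by T cells. Doublets left in T1, where 3 were called against 92 in C, may add such RNA. The rule for named genes added Areg, the growth factor amphiregulin (ENSMUSG00000029378, 2.48 [2.26, 2.71]), which the deposited files list under the symbol Mcub, Crem, a cAMP-response transcription factor (2.45 [2.32, 2.58]), and Ramp3 (2.50), Ttn (2.25) and Neb (2.93) among the genes higher in both T1 and T3. In all, 222 of 9110 genes were at least 2-fold higher and 190 at least 2-fold lower in T1, by a rule of size and not of a test.

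The T-like cells of T3 were compared with those of C to ask the same of the high-grade library. Cytotoxic transcripts were lower still, and naive and memory T-cell transcripts were higher. Gzma and Gzmb, granule proteases of killer cells, fell by 4.25 and 3.84 on the log2 scale, and Ifng fell by 3.85. S1pr1, the receptor for exit from tissue into lymph and blood, had a log2 ratio of 1.54 [1.43, 1.65], and Satb1, a chromatin organiser, 2.27 [2.20, 2.34]. In the naive and memory list 7 of 10 members rose and 2 fell, with a median of 1.55 at percentile 100; Klf2 and Bcl2 fell, by 1.21 and 1.31. In T1 the same list had a median of 0.29 (percentile 99.87), with 2 of 10 higher and 2 lower. The cytotoxic list had a median of −2.50 at percentile 0, and 11 of 13 members fell and 0 rose. The regulatory list had a median of 0.58 (percentile 99.98), with 4 of 14 higher and 2 lower, and Foxp3 a log2 ratio of 0.89 [0.57, 1.21]. Il10 fell by 2.47 and the checkpoint receptor Lag3 by 2.08 in T3, whereas Lag3 had a log2 ratio of 1.28 [1.14, 1.41] in T1.

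In the type 17 list 3 of 8 members rose and 1 fell in T3 (median 0.74, percentile 99.97), and Il17a was higher by 2.16 [1.95, 2.37]. The inhibitory receptors had a median of −0.95 (percentile 0), with 1 of 9 higher and 5 lower, and MHC class II genes a median of −0.87 (percentile 0.09, 1 of 9 higher and 3 lower), while immunoglobulin constant genes had one of −1.69 (percentile 0, 6 of 8 lower). Immediate early genes fell in 8 of 17 cases (median −0.89, percentile 0). Hypoxia genes had a median of −0.25 (percentile 23.8), with 3 of 14 higher and 0 lower. Interferon-stimulated genes had medians of −0.03 in T1 (percentile 74.1, 0 of 20 past the rule) and −0.23 in T3 (percentile 23.2, 3 of 19 lower). Xcl1, a chemokine of killer and innate-like lymphocytes, fell in both libraries, to 119 CPM in T1 and 22.8 CPM in T3 from 659 CPM in C. The rule also named as lower in both the Ly49 and NKG2 family receptors Klra7 (−2.44 and −5.04 in T1 and T3), Klra6 (−2.34 and −4.78), Klra9 (−2.33 and −5.52) and Klrc2 (−2.28 and −2.93), the gamma-chain gene Tcrg-C4 (−2.25 and −4.91) and Cdh1 (−2.33 and −5.11). The Ly49 genes are near-identical copies, so counts may be split among them. Mei1 had 1 UMI in T3, a log2 ratio of −7.90 [−13.21, −5.41].

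In T3, 289 of 8704 genes were at least 2-fold higher and 615 at least 2-fold lower in T-like cells. Set directly against T1, T3 had higher Tpm3-rs7, Nmnat1, St8sia6, Slc35g1 and Vipr1 and lower Tmsb15b1, Il10, Tcrg-C2, Lag3 and Dapk2, as picked by the rule for named genes; 175 of 8713 genes were at least 2-fold higher and 484 lower. Of genes measured in both comparisons, 60 were higher in both T1 and T3, against 5.01 for independent lists and 0 in simulated unchanged libraries sharing C, and 144 were lower in both, against 12.3 and 0. The simulated libraries held counting noise only, so the 0 does not bound overlap from differences between libraries. The log2 ratios correlated across genes with r = 0.575, against 0.470 simulated, and their covariance was 0.189, against 0.0100; genes are not independent replicates, and part of the excess may come from the shared control library. The T-like class held different clusters in each library, with clusters 4 and 12 holding most of C, clusters 10, 7 and 9 most of T1 and clusters 3, 6 and 8 most of T3. Cluster 7, with 18.3% of the T-like cells of T1, had more markers of another class than of its own among its leading genes over all other cells. Stricter naming set it aside. Haemoglobin transcripts were at 0.658 CPM in T-like cells of C, 0.648 CPM in T1 and 714 CPM in T3.

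Shares of T-like cells with at least 1 UMI were compared after thinning each cell to 1000 UMIs, which left out 78, 98 and 264 shallower T-like cells of C, T1 and T3. Foxp3 was then found in 1.18%, 6.01% and 1.96% of T-like cells (3.07%, 14.5% and 3.79% before thinning), and Il10 in 1.47%, 7.74% and 0.474% (2.22%, 13.4% and 0.718%). Cd8a was found in 15.4%, 6.57% and 7.12% (31.5%, 16.6% and 16.9%), Cd4 in 5.04%, 12.2% and 11% (21.5%, 42.8% and 33.5%), and Trdc in 10.8%, 3.73% and 2.02% (15.7%, 6.24% and 3.69%). Gzmb was found in 8.72%, 12.7% and 0.949% (15.6%, 19.8% and 1.90%), and S1pr1, which B cells also express, in 6.02%, 10.5% and 20.7% (25.0%, 32.7% and 54.1%). As a background from free RNA or doublets, thinned B-like cells, from which 63, 73 and 115 cells were left out, had a Foxp3 UMI in 0.0349%, 0.0663% and 0%, a Cd8a UMI in 0.140%, 0.299% and 0.896%, and a Gzmb UMI in 0.419%, 0.464% and 0%. S1pr1 has no such background, since the thinned B-like cells had it in 13.7%, 12.2% and 11.3%. The median depth before thinning was 5680, 6214 and 4488 UMIs in T-like and 4697, 5070 and 3681 in B-like cells.

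**Figure D2:**
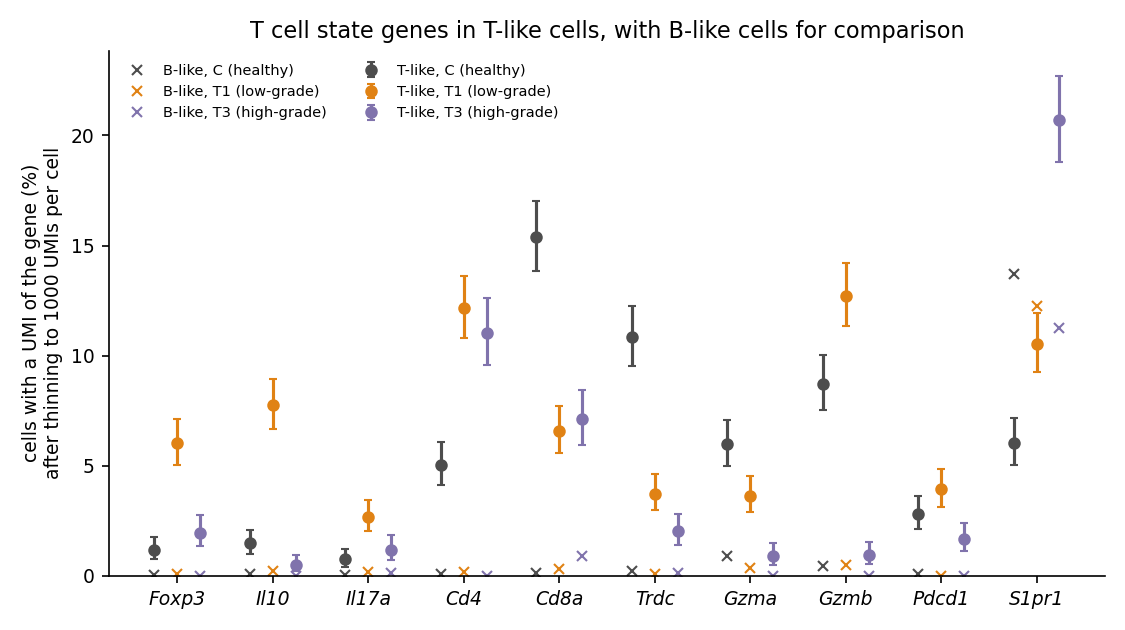
Percentage of T-like cells of C, T1 and T3 with at least 1 UMI of each gene after thinning every cell to 1000 UMIs; bars on the points are exact 95% counting intervals and crosses give the same percentage in B-like cells, some of which can express Il10 and S1pr1. Foxp3 and Il10 were highest in T1, S1pr1 was highest in T3, and Gzma and Gzmb were lowest in T3.

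The B-like cells were compared to ask which B-cell genes differed in each library, since the series title concerns regulatory B cells, leucine and a leucyl-tRNA synthetase. In B-like cells of both neoplastic libraries, Klf2, the immediate early genes Jun and Fos, which also respond to tissue dissociation, and the germinal centre markers Rgs13 and Mef2b were lower. Klf2, a transcription factor of lymphocyte quiescence and trafficking, was at 3171 CPM in C, 885 CPM in T1 and 833 CPM in T3, log2 ratios of −1.84 [−1.87, −1.81] and −1.93 [−1.99, −1.87]. Like Jun, it was a leading gene of the B-like sub-cluster led by Hspa1a. A difference in tissue handling was not separated from one in B-cell state. Klf2 lies on chromosome 8 from 72319033 to 72321656 and Crem on chromosome 18 from 3266048 to 3337748. Mki67, a proliferation gene, fell by 1.24 in T1 and 2.09 in T3 on the log2 scale. Crem had log2 ratios of 1.58 [1.46, 1.71] and 1.56 [1.38, 1.73], and Got1, a cytosolic transaminase, 1.48 [1.35, 1.62] and 1.73 [1.55, 1.92]. The rule for named genes found only 6 genes higher in both, the others being Fam167a (1.27 and 1.40), Pde3b (1.08 and 1.8), Fnip1 (1.04 and 1.52) and Pmepa1 (1.39 and 1.02). Among the genes lower in both were Rgs13 (−1.53 and −2.98) and Mef2b (−1.18 and −2.67), Ada (−1.13 and −3.54), Jun (−1.85 and −1.41) and Fos (−1.32 and −1.47), Eps8l1 (−1.90 and −1.25), and the interferon-induced Rtp4 (−1.63 and −1.20).

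Proliferation genes had a median of −0.79 in T1 and −2.60 in T3, both at percentile 0, with 5 of 15 and 14 of 15 members lower. Interferon-stimulated genes had medians of −0.82 and −0.74, both at percentile 0, with 9 of 19 and 5 of 19 lower, including Ifit3 (−2.49 and −1.88). Small B-like sub-clusters changed in size too, the one led by Ifit3 and Mx1 from 123 cells in C to 20 in T1 and 10 in T3, the one led by Rgs13 and Mef2b from 127 to 79 and 7, and the proliferating one from 74 to 35 and 3, so the class sums also reflect how many such cells were caught. The large sub-cluster led by genes such as Hspa1a, Jun and Klf2 held 59.1%, 31.4% and 38.1% of the B-like cells of C, T1 and T3. The one led by genes such as Crem and Got1 held 18.3%, 52.0% and 44.8%. Immediate early genes had medians of −0.98 (percentile 0, 8 of 16 lower) and −0.28 (percentile 2.12, 4 of 16 lower). Naive B-cell genes had medians of −0.24 (percentile 1.13) and 0.33 (percentile 96.8), with 1 of 11 lower in each. Immunoglobulin constant genes had medians of −0.19 (percentile 8.34, 0 of 12) and −0.55 (percentile 0.05, 2 of 10 lower); Igha fell by 2.36 in T3, and it was also read in T-like cells at 233, 274 and 11.5 CPM, where it was also lowest in T3. MHC class II genes had medians of 0.02 and −0.10 with 0 of 12 past the rule in each. Plasma secretory genes had medians of 0.03 (0 of 12) and −0.30 (0 of 10), and hypoxia genes −0.07 and −0.18 (0 of 13 each).

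Regulatory B-cell genes had a median of 0.11 in T1 (percentile 99.8, 2 of 15 higher and 1 lower) and 0.07 in T3 (percentile 70.3, 0 of 11). Il10, 1 of the 2 higher in T1, was at 1.24, 8.28 and 0.625 CPM in B-like cells, a log2 ratio of 2.74 [2.04, 3.52] in T1. In T-like cells it was at 31.3, 147 and 5.67 CPM, so the B-like level lay under 20% of the T-like level in each library. In B-like cells of T1 regulatory T-cell genes had a median of 1.74 (4 of 8 higher) and type 17 genes of 3.26 (2 of 4 higher), while cytotoxic genes had one of −0.75 (1 of 7 higher and 1 lower). A B-like sub-cluster of 21, 17 and 4 cells was led by T-cell genes such as Cd28 and Trac. T-cell RNA in B-like barcodes was not separated from expression by B cells, for Il10 too. Doublets left in T1, where 3 were called against 92 in C, are a possible source of such RNA and were not tested. Cd274, the PD-L1 gene, had log2 ratios of 0.05 and 0.94, and Tgfb1 0.21 and 0.54, below the 2-fold rule. Leucine transport and mTORC1 genes had medians of −0.05 (percentile 83.6, 0 of 20) and 0.08 (percentile 61.0, 1 of 17 lower), with Slc7a5, a leucine transporter chain, at 0.07 and 0.15. Branched-chain amino acid breakdown genes had medians of −0.03 (percentile 87.4, 0 of 11) and −0.16 (percentile 19.6, 1 of 10 lower). Cytosolic aminoacyl-tRNA synthetases had medians of −0.21 (percentile 3.70) and −0.14 (percentile 7.04), with 0 of 20 past the rule in each. Among them Lars, the cytosolic leucyl-tRNA synthetase, was at 29.5, 23.7 and 28.4 CPM in B-like cells of C, T1 and T3, with log2 ratios of −0.32 [−0.52, −0.12] and −0.06 [−0.40, 0.27]. The mitochondrial synthetases had medians of −0.20 (percentile 31.4, 0 of 15) and 0.10 (percentile 67.8), where the only one of 12 past the rule was Lars2. Nuclear respiratory chain genes had medians of −0.18 (percentile 1.86) and −0.46 (percentile 0), with 0 of 24 past the rule, mitochondrially encoded messages 0.04 in both (0 of 13), and NAD metabolism genes −0.09 (0 of 14) and 0.11 (1 of 11 lower).

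In B-like cells 29 of 8963 genes were at least 2-fold higher and 120 lower in T1, and 241 of 8156 were higher and 314 lower in T3. Stricter naming, which set aside clusters 1, 15 and 19, the first with 58.7% of the B-like cells of T1, left 17 higher and 38 lower in T1. TMM scaling shifted the median log2 ratio by 0.13 in T1 and −0.10 in T3, and the share of higher genes among those past the rule went from 19.5% to 39.3% in T1 and from 43.4% to 27.4% in T3, so the balance of higher and lower genes depended on the scaling. Set directly against T1, T3 had higher Tpm3-rs7, Mdm1, Mid1, Hsph1 and Zrsr1 and lower Ada, Mef2b, Dstn and Hist1h1b in B-like cells, and 235 of 8003 genes were at least 2-fold higher and 102 lower. Of genes measured in both comparisons, 8 were higher in both, against 0.291 for independent lists and 0 simulated with counting noise only, and 60 were lower in both, against 3.93 and 0. Across genes r was 0.584 against 0.291 simulated and the covariance 0.109 against 0.00766, and part of the excess may come from the shared control library. Cluster 0 held most B-like cells of C, and cluster 1 most of those of T1 and T3.

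**Figure D3:**
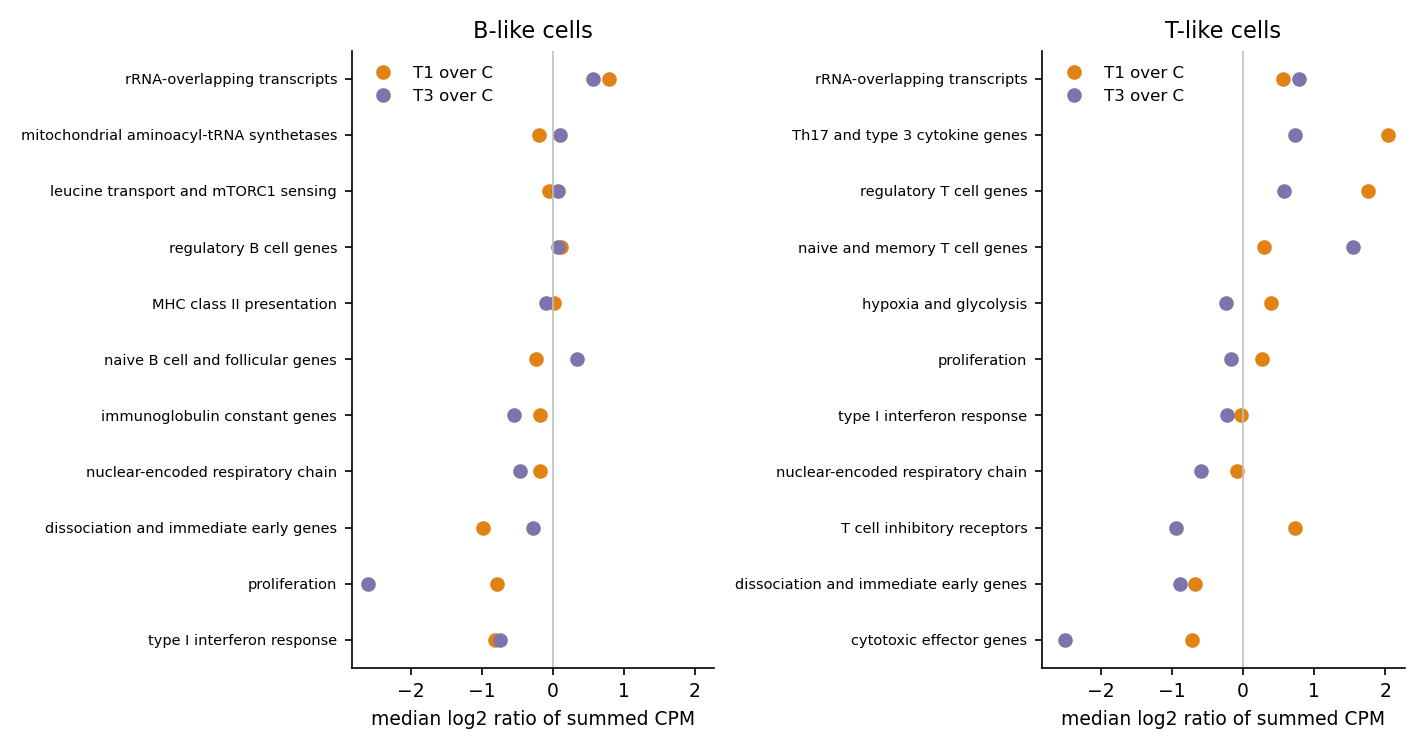
Median log2 ratio of CPM to C over the measured members of each gene list, in B-like and T-like cells of T1 and T3. In T-like cells the regulatory and type 17 lists were highest in T1 (1.77 and 2.04) and the cytotoxic list was lowest in T3 (−2.50); in B-like cells the proliferation list was lowest in T3 (−2.60).

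**Figure D4:**
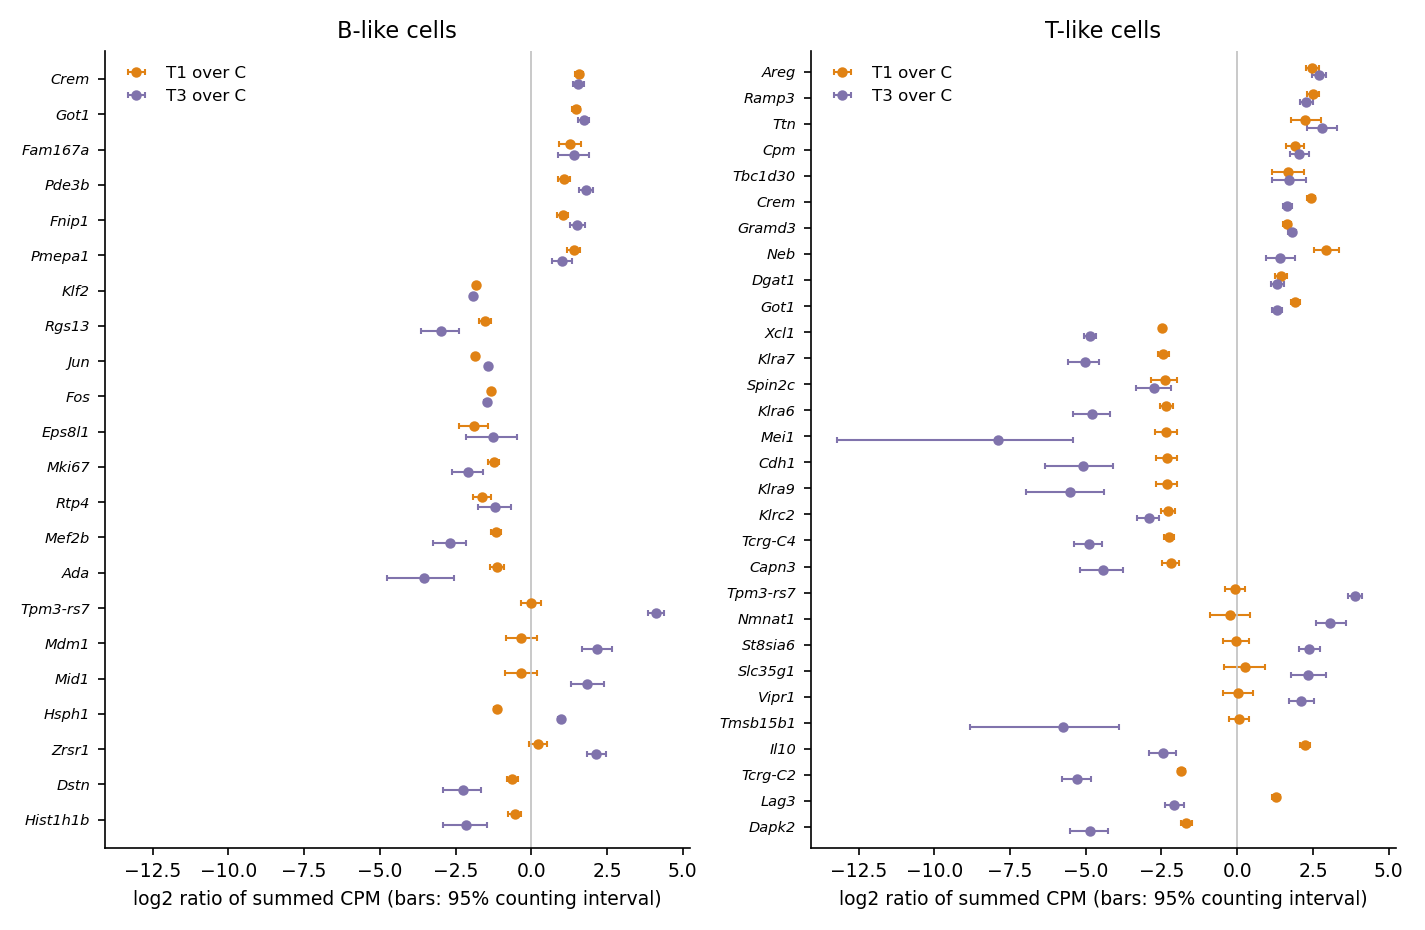
Log2 ratio of CPM to C for genes picked by the rule for named genes, in B-like and T-like cells of T1 and T3; bars are exact 95% counting intervals. Crem and Got1 were higher, and Klf2 in B-like and Xcl1 in T-like cells lower, in both libraries.

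Lars2, the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666, plus strand, GRCm38), was the other leucyl-tRNA synthetase gene that the series title could concern. In B-like cells it was at 413 CPM [403, 424] in C, 712 CPM [699, 725] in T1 and 907 CPM [874, 940] in T3. The fold was 1.72 [1.67, 1.78] for T1 and 2.19 [2.10, 2.29] for T3, so only T3 passed the 2-fold rule. T-like cells showed a similar order, at 505, 752 and 1175 CPM, with folds of 1.49 [1.44, 1.54] and 2.33 [2.25, 2.40]. The fold of T1 over C was 1.75 [1.56, 1.96] in plasma-cell-like and 1.69 [1.47, 1.94] in ILC2-like cells. In mononuclear-phagocyte-like cells it was 1.25 [1.02, 1.55], and for T3 over C 0.980 [0.719, 1.32]. After thinning to 1000 UMIs, 32.0%, 51.4% and 54.8% of B-like and 38.1%, 49.6% and 60.6% of T-like cells of C, T1 and T3 had a Lars2 UMI, against 81.1%, 92.3% and 84.9% of B-like and 86.6%, 93.0% and 91.1% of T-like cells unthinned. No analysed class is known to lack Lars2, so no background share was available.

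In B-like cells 2 of the 3 transcripts that overlap the ribosomal RNA repeat had folds above 1 in both neoplastic libraries, under the 2-fold rule. Gm42418 (chromosome 17, 39846958 to 39848788) was at 9425, 17213 and 13967 CPM in B-like cells, folds of 1.83 and 1.48, and AY036118 had folds of 1.73 and 1.69. The third member, Gm26917, had folds of 0.456 and 0.948 there. In T-like cells of C, T1 and T3 AY036118 was at 1326, 1960 and 2293 CPM, Gm42418 at 10166, 16188 and 15333 CPM and Gm26917 at 341, 327 and 756 CPM. This list had a median log2 ratio of 0.79 in T1 (percentile 99.99, 1 of 3 lower) and 0.57 in T3 (percentile 97.1, 0 of 3). Lars2 also depended on the depth of the barcode. In barcodes with a B-cell marker UMI and no CD3 UMI, named or not, that held 500 to 1500 UMIs it was at 3553, 5937 and 3243 CPM in C, T1 and T3, and in those above 4000 UMIs at 365, 639 and 747 CPM. In those of 1500 to 4000 UMIs it was at 586, 1176 and 1088 CPM. The order of T3 over T1 over C therefore held only above 4000 UMIs, where T3 had 334 such barcodes.

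**Figure D5:**
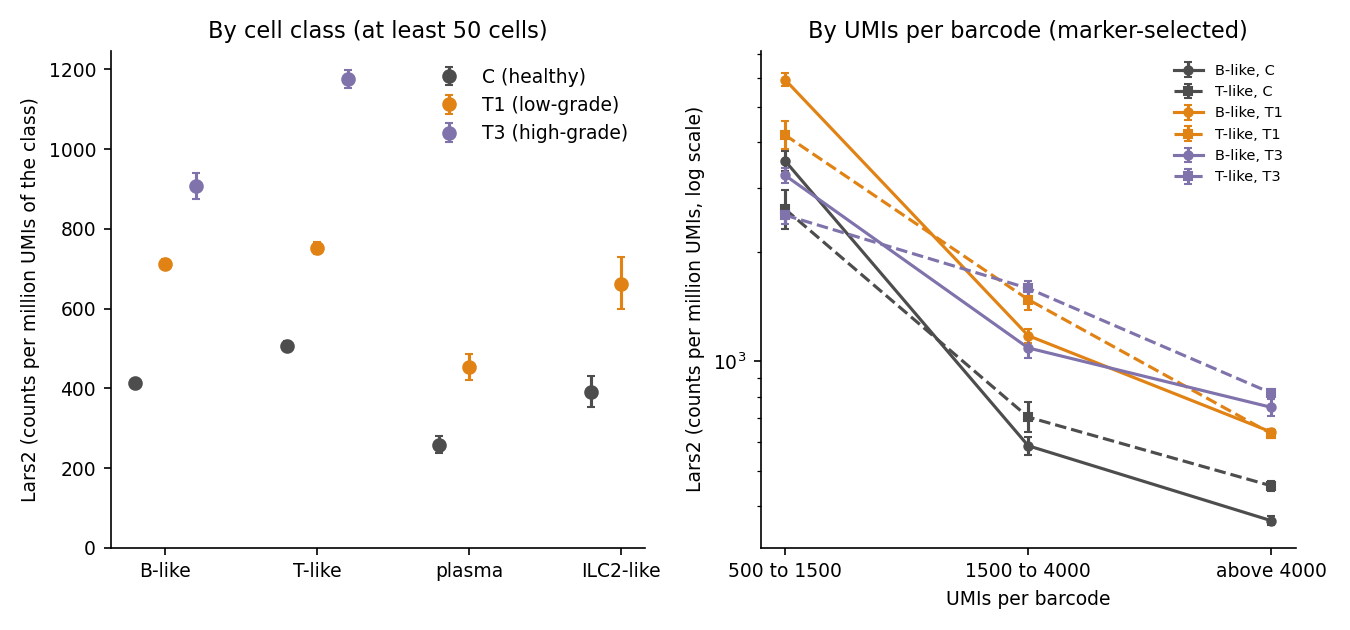
Lars2 in CPM in C, T1 and T3 by cell class of at least 50 cells (left, linear axis) and by UMIs per barcode among barcodes with B-cell or CD3 transcripts (right, log axis), with exact 95% counting intervals. Among barcodes above 4000 UMIs the level with B-cell transcripts was 365 CPM in C, 639 CPM in T1 and 747 CPM in T3, and shallow barcodes had a higher Lars2 share in all 3 libraries.

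The myeloid cells were compared to ask how inflammatory and suppressive programmes differed, in few cells (46, 43 and 16 mononuclear-phagocyte-like cells). Il1b, an inflammatory cytokine, had log2 ratios of 1.86 [1.66, 2.06] in T1 and 2.32 [2.10, 2.55] in T3, and Ly6c2, a monocyte surface gene, 1.40 and 2.37. Il1b, Cxcl2 and Acod1 were also leading genes of the neutrophil-like cells, and Il1b was one of cluster 2 too. RNA from other cells was not separated, which also limits the inflammatory myeloid list below. Cxcl2, a neutrophil chemoattractant, fell by 2.26 in T1 and had a log2 ratio of 2.78 [2.63, 2.93] in T3. Cxcl3, from the same family, had 0 UMIs in C, and was at 2.31 CPM in T1 and 1242 CPM in T3. The complement genes C1qa, C1qb and C1qc fell in T1, by 3.60, 2.49 and 2.52 on the log2 scale. Inflammatory myeloid genes had a median of −1.14 in T1 (percentile 0, 1 of 6 higher and 4 lower) and 2.32 in T3 (percentile 100, 7 of 9 higher and 0 lower). Tumour-associated or suppressive genes had medians of 0.50 (2 of 4 higher and 1 lower) and 1.51 (1 of 3 higher), with Spp1 at 3.49 [2.51, 4.66] and 4.54. Complement and resident macrophage genes had medians of −2.49 (4 of 4 lower) and 0.69 (2 of 4 higher). Klf4, Atf3, Emp1, Klf2, Egr1 and Clec10a were lower in both libraries, and Plac8, Csf2rb and Bst2 higher in both.

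Of 1112 genes measured in these cells, 28 were at least 2-fold higher and 44 lower in T1, and of 788 genes, 66 were higher and 73 lower in T3. Among neutrophil-like cells (6, 6 and 55) Ccl4 was higher in both neoplastic libraries, with log2 ratios of 3.30 and 2.72, and Clec4e (−1.40 and −1.24) and Ptgs2 (−1.09 and −2.58) were lower. Class comparisons with fewer than 50 cells in a library, as in both of these classes, rest on too few cells to separate the state of a class from which of its cells were caught.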

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

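All tests of the low-UMI cluster and of the T3 composition, the search for sequence shared with Lars2 and the test of rRNA-linked counting as the whole cause of the T3 level were chosen after the results had been seen, and several of the values behind them were already known. The tests of rRNA-linked counting in T1 and of depth for Lars2 were set before. The reasons given below for leaving rRNA-linked counting in T1 open were not part of its written bound. Some gene and list ratios in T-like cells pointed in opposite directions in T1 and T3, each against C with 1 library per side, and the difference between the directions was not tested. The log2 ratio of Il10 was 2.23 in T1 and −2.47 in T3. That of Lag3 was 1.28 and −2.08. The median of MHC class II genes was 1.09 and −0.87, and that of immunoglobulin constant genes, transcripts of B cells, 0.31 and −1.69. The median of inhibitory receptors was 0.73 and −0.95.

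In barcodes left out of all classes by the filters, Lars2 was at 2976 CPM in T1, above the 2492 CPM of the left-out barcodes of C. Hbb-bs, a haemoglobin gene, was at 2.32 CPM in the left-out barcodes of C, 573 CPM in T1 and 119302 CPM in T3. In the unnamed cluster 2 of T3, haemoglobin transcripts together were at 41858 CPM.

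The higher Lars2 level of B-like cells in T1 and T3 was weighed first. Unequal detection from depth is argued against by the thinned shares, whose ratio to C was 1.61 in T1 and 1.71 in T3. Thinning keeps the part of a cell's UMIs that is Lars2, and that part was higher in shallow barcodes. It therefore cannot decide whether depth raised T3, whose B-like cells had a median of 3681 UMIs against 4697 in C. Sequence shared with another annotated gene was found for 0 genes at 91 bases and 95% identity. Only annotated transcripts were searched, so a match to rRNA sequence outside them could not be seen. Whether counting linked to rRNA accounts for part of the T1 level stays open, although the bound written beforehand, a B-like fold apart from those of T-like and mononuclear-phagocyte-like cells, was met at 1.72 [1.67, 1.78] against 1.49 [1.44, 1.54] and 1.25 [1.02, 1.55]. For T-like cells the bound was wrong because Gm42418 and AY036118 shared the gap, with quotients of B-like over T-like folds of 1.15 and 1.17 against 1.16 [1.11, 1.21] for Lars2, whereas the quotients over mononuclear-phagocyte-like cells, 1.96 and 1.06 against 1.37, and Gm26917, at 0.456 in B-like cells and 0.844 with the low-UMI cluster kept, go against this counting, the former in 46 and 43 cells, too few to decide. As the whole cause of the level of T3 over T1 it stays open too, since the folds of Gm42418, AY036118 and Gm26917 were 0.811, 0.977 and 2.08 against 1.27 [1.22, 1.33] for Lars2, but 1.002, 1.18 and 2.20 against 1.65 with the low-UMI cluster kept, and a difference by stage of neoplasia is open and untested.

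The low-UMI cluster 5, led by Gm26917 and Lars2, held 6.61% of the B-like cells of C, 10.0% of T1 and 29.2% of T3 when counted with them. Depth as the whole cause is argued against by the T1 share, which was 1.51-fold that of C when the median depth per barcode was 3.21% lower. Barcodes of any lineage that hold little cytoplasmic RNA, such as damaged cells, are a candidate source, since barcodes of 500 to 1500 UMIs with CD3 and no B-cell transcripts had at least 3.08-fold the Lars2 CPM of those above 4000 UMIs in each library, just above the bound of 3. Their share of ribosomal protein counts was also lower, at 10.1% against 33.7% in C, 12.4% against 35.4% in T1 and 25.2% against 40.3% in T3. Whether stage adds to this was not tested.

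T3 had higher naive and memory genes and lower cytotoxic genes in T-like cells, more neutrophil-like cells, and fewer plasma-cell-like and ILC2-like cells. For S1pr1 the share of T-like cells of T3 with a UMI after thinning was 3.44-fold that of C, so unequal detection does not account for this gene. Thinning keeps the part of a cell's UMIs that is S1pr1, which was already known to be higher in T3. It also left out 264 shallow T-like cells of T3. It therefore cannot decide whether lower depth adds to the naive T-cell part as a whole. Blood carried into the T3 suspension may contribute, since haemoglobin CPM in T-like cells of T3 was 1085-fold the higher of C and T1, and 34.6-fold in B-like cells. The CD45+ gate would remove most free red cells but not blood leukocytes. A difference by stage stays open, and blood and stage were not separated by any value.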

How the results depend on the processing

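Stricter naming, shares of named cells, the kept low-UMI cluster, cells of at least 2000 UMIs and removal of top-scoring doublets were added after the data had been seen. Alternatives were run for the shares of 5 classes, Lars2 in B-like cells, gene counts and 11 gene lists only. Among these no ratio whose interval excluded 0, and no list median beyond 0.25, changed sign; the T1 shares of B-like and T-like cells and some list medians near 0 did. Of the alternatives, 102 of 118 for class shares and 21 of 30 for Lars2 CPM stayed within the counting interval, as did 0 of 4 for the share of B-like cells with a Lars2 UMI. For gene counts 68 of 92 stayed within 1.5-fold, and for list medians 125 of 132 within 0.25. Those that did not were, with members of at least 100 UMIs, regulatory B-cell genes in T3 (0.07 to 0.36, and −0.03 with TMM), cytotoxic genes in T1 (−0.71 to −1.04) and type 17 genes (0.74 to 0.47) and inhibitory receptors (−0.95 to −1.26) in T3. The others were proliferation genes in B-like cells of T3 at 10% mitochondrial (−2.60 to −2.24) and type 17 genes in T1 at 10% and with 500 genes (2.04 to 1.65 and 1.74). The plasma-cell-like, neutrophil-like and ILC2-like ratios of T3 to C ran from −3.82 to −2.68, 3.55 to 4.08 and −4.11 to −3.50. No paired analysis was possible because each group has 1 library.

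The B-like share ratio of T1 to C (0.02) was 0.086 with at least 500 genes and −0.98 with stricter naming. For T3 (−1.33) it was −1.11 at 10% mitochondrial, −0.97 with 500 genes, −1.66 with all variable genes, −2.06 with stricter naming and −0.83 among named cells. The T-like ratio of T1 (0.03) was 0.13 at 10% and −0.13 with stricter naming. For T3 (0.26) it was 0.39 at 10%, 0.54 with 500 genes, 0.19 with doublets kept, 0.19 and 0.17 at resolutions 0.5 and 2, 0.15 without top-scoring doublets and 0.76 among named cells. The cause was not tested.

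Lars2 log2 CPM ratios in B-like cells of T1 (0.78) were 0.92 with TMM, 0.62 as a mean over cells, 0.87 with the low-UMI cluster and 0.84 in cells of at least 2000 UMIs. In T3 (1.13) they were 1.06 with 500 genes, 1.03 with TMM, 1.04 as a mean, 1.28 with stricter naming and 1.60 with the low-UMI cluster. The ratio of cells with a UMI (0.69 and 0.78) was 0.46 and 0.50 thinned to 2000 UMIs and 0.19 and 0.067 unthinned, where most cells have a UMI. The cause of the others was not tested.

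Genes higher in B-like cells of T1 (29) numbered 44 with 500 genes, 53 with TMM, 51 at 50 UMIs, 9 at 300 UMIs, 142 at 1.5-fold and 17 with stricter naming, and genes lower (120) 188, 46, 565 and 38 at 50 UMIs, 300 UMIs, 1.5-fold and stricter naming. In T3, B-like genes higher (241) were 158 with TMM, 122 at 300 UMIs and 1218 at 1.5-fold, and lower (314) 132 and 969 at 300 UMIs and 1.5-fold. T-like genes at 300 UMIs and 1.5-fold were 131 and 480 higher (222) and 97 and 638 lower (190) in T1, with 290 lower at 50 UMIs, and 169 and 926 higher (289) and 333 and 1729 lower (615) in T3. UMI and fold minimums change how many genes can pass; the cause was not tested for the others.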

Other observations

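No test is reported in this part, and its genes were chosen after their values had been seen, except those of the gene lists and the rule for named genes. Tpm3-rs7, annotated on chromosome 14 from 113314608 to 113316754 (GRCm38), was at 9.97, 9.87 and 171 CPM in B-like cells of C, T1 and T3 and at 12.5, 12.0 and 185 CPM in T-like cells. Nmnat1, an enzyme of NAD synthesis, had log2 ratios of −0.23 in T1 and 3.07 in T3 in T-like cells, while the NAD list as a whole had medians of −0.04 (0 of 14 higher and 1 lower) and −0.33 (1 of 14 higher and 3 lower) there. Nuclear respiratory chain genes in T-like cells had medians of −0.09 (percentile 2.83) and −0.59 (percentile 0), with 0 of 24 past the rule. Leucine transport and mTORC1 genes in T-like cells had medians of 0.09 (0 of 20) and −0.10 (1 of 20 higher and 2 lower). Proliferation genes in T-like cells had medians of 0.26 (0 of 8) and −0.17 (0 of 5).

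In mononuclear-phagocyte-like cells, immediate early genes had medians of −0.83 in T1 (5 of 16 lower) and −1.43 in T3 (1 of 16 higher and 13 lower), and MHC class II genes −0.42 (0 of 10) and −1.01 (4 of 8 lower). Cd209a, a dendritic-cell lectin, had log2 ratios of −0.58 and −3.62 there, and Cxcl1, a neutrophil chemoattractant, 7.02 [5.64, 8.91] in T3. Lars2 was higher in T1 than in C in B-like sub-clusters of different kinds. It was at 406 CPM in C and 736 CPM in T1 in the largest one of C, led by Hspa1a and Jun, at 407 and 708 CPM in the largest one of T1, led by Crem and Plaur, and at 404 and 696 CPM in the one led by germinal centre genes such as Rgs13 and Mef2b. In the proliferating one, led by Pclaf and Birc5, it was at 503 CPM [460, 549] in C and 466 CPM [410, 527] in T1.

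The labels describe male mice, and the following values go against that sex in all 3 libraries. Xist, the transcript of the inactive X chromosome (X, 103460366 to 103483254), was at 1279, 1196 and 1362 CPM over all cells of C, T1 and T3. Ddx3y, Eif2s3y and Uty, which lie on the Y chromosome, had 0 UMIs in the analysed cells of all 3 libraries, and Kdm5d had 0, 1 and 1 UMIs. Haemoglobin transcripts over all cells were at 21.0, 3.58 and 13690 CPM, with a median of 31 haemoglobin UMIs per cell in cluster 2.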
